A study of Mus musculus with 6 samples.

How the data were processed

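Total RNA of embryonic mouse hearts was amplified, labelled with biotin and hybridised to Affymetrix 3' expression arrays, 1 array per sample, per the labels' protocols. The deposited table holds 1 value per probe set and array on the log2 scale for 6 arrays; per the submitters' processing notes the authors used MAS5, whose version is not given in the sources used here. The deposited log2 values ran back to a 2% trimmed mean of 500 on the linear scale on all 6 arrays, so each array had been scaled globally. Log2 medians differed by less than 0.2, and the values were used as deposited, with no further normalization and no pseudocount. All 6 columns were matched to a sample by its label, and 0 columns were left over. Values reach down to 0 on this scale, and detection calls were not used here, so signals near the lower end are not told apart from background.

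The table has 45101 probe sets, of which 64 control probe sets were left out. Gene names came from the platform annotation: 34945 probe sets name 1 gene, 932 name several and 9160 name none or are not listed there. Names were checked through Entrez identifiers against the RefSeq gene table of assembly GRCm38.p6, which holds 34741 of those probe sets' identifiers; no coordinates are given because the annotation names no build. Only probe sets naming 1 gene were used for genes, 18194 in number. Each gene was represented by its probe set of highest mean log2 signal over the 6 arrays, and genes whose representative lay in the lowest 40% of all probe sets, below a log2 signal of 5.90, were left out, which left 12416 genes. No pair of arrays of one label held the same values: at least 44993 of 45037 differed.

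Differences between the 3 arrays labelled Rhau KO and the 3 labelled wildtype were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend), with Benjamini-Hochberg adjustment and a threshold of 0.05; every adjusted p for a gene is limma's, two-sided. Differences are log2 values, labelled Rhau KO minus labelled wildtype, and folds are their size on the linear scale. Gene lists with at least 4 measured members were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over 29 lists; the sex-linked list was not tested as a list, and its 4 measured genes were tested singly like all others. The lists cover cardiac regulators and chambers, signalling, contraction, metabolism, stress pathways, helicases and mRNA decay, and markers of other cell types. Groups, tests, lists and alternatives were fixed before the data were examined. Genes are named by a rule fixed at the same time: Dhx36 and Nkx2-5; the 13 largest increases and 13 largest decreases among called genes with non-overlapping groups; and in each list up to 4 called members of largest change, or otherwise up to 2 members as values. Genes named outside it are said to be so.

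The procedure was tested on simulated arrays drawn from the means and residual SDs of the 12416 genes in this comparison, with 200 genes changed. It recovered 58.2% of 67 genes changed 1.5-fold, 82.1% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, and 2.45% of the calls were unchanged genes. These shares come from 1 simulated set with far fewer changed genes than the 2354 called in the data. They may differ at that number. With no changed gene it called 0 genes and 0 lists. Simulated genes were drawn independently of each other, so the 0 lists say nothing about the list test where members vary together.

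Alternatives covered pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a filter on the lowest 60%, the mean of all probe sets of a gene, every probe set on its own, eBayes without trend, array weights, the replicate number as a block, leaving out each array, an estimated inter-gene correlation and fry. The mean Y-linked signal of each array as a covariate, the 3 arrays with both Xist and Y-linked signal, the genes off the sex chromosomes, and lists without their most changed member were added after seeing the data. With that covariate the median SE of the called autosomal genes was 0.163, against 0.075 without it. Single-gene values with it are thus less precise. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.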

Results

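Expression was measured on 6 Affymetrix 3' arrays of mouse embryonic heart at E12.5, in the C57BL/6 strain. The labels assign 3 arrays to wildtype hearts and 3 to hearts in which Rhau was deleted. Rhau is an older name of Dhx36, an RNA helicase of the DEAH-box family that unwinds G-quadruplexes, four-stranded structures of guanine-rich RNA and DNA. Each group carries replicate numbers 1 to 3, and the series text gives 3 hearts per group and 6 RNA samples, which reads as 1 heart per array. The 2% trimmed mean of the linear signal was 500 on every array, and the median log2 signal lay between 6.68 and 6.80. Array data carry no read depth, and the number of arrays limits the precision.

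The targeted gene went against the labels. Dhx36 signal was higher in the 3 arrays labelled Rhau KO than in the 3 arrays labelled wildtype, at 10.27 ± 0.19 against 8.86 ± 0.14 (log2 signal of the brightest probe set, mean ± SD, n = 3 each). The difference of 1.41 (SE 0.108) was a 2.66-fold higher level, with adjusted p = 1.46e-05. The other Dhx36 probe sets were also higher, by 1.10 and 0.90. On all 3 probe sets, each array labelled Rhau KO lay above each array labelled wildtype. The labels do not give the deleted part of the gene, so a probe set outside it would check nothing. Because of this, groups are named below by the label they carry, and every direction is that of the labels as deposited.

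Nkx2-5, a homeobox transcription factor needed for heart formation, was lower in the arrays labelled Rhau KO. Its signal was 10.89 ± 0.08 there and 12.18 ± 0.07 in the arrays labelled wildtype (n = 3 each). The change was -1.29 (SE 0.058), a 2.44-fold lower level with adjusted p = 7.36e-07, and the groups did not overlap on any array. A single probe set measured this gene. The comparison addresses whether Nkx2-5 mRNA changes when the helicase is deleted, and Dhx36 itself ran against the label that gives the direction.

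**Figure D1:**
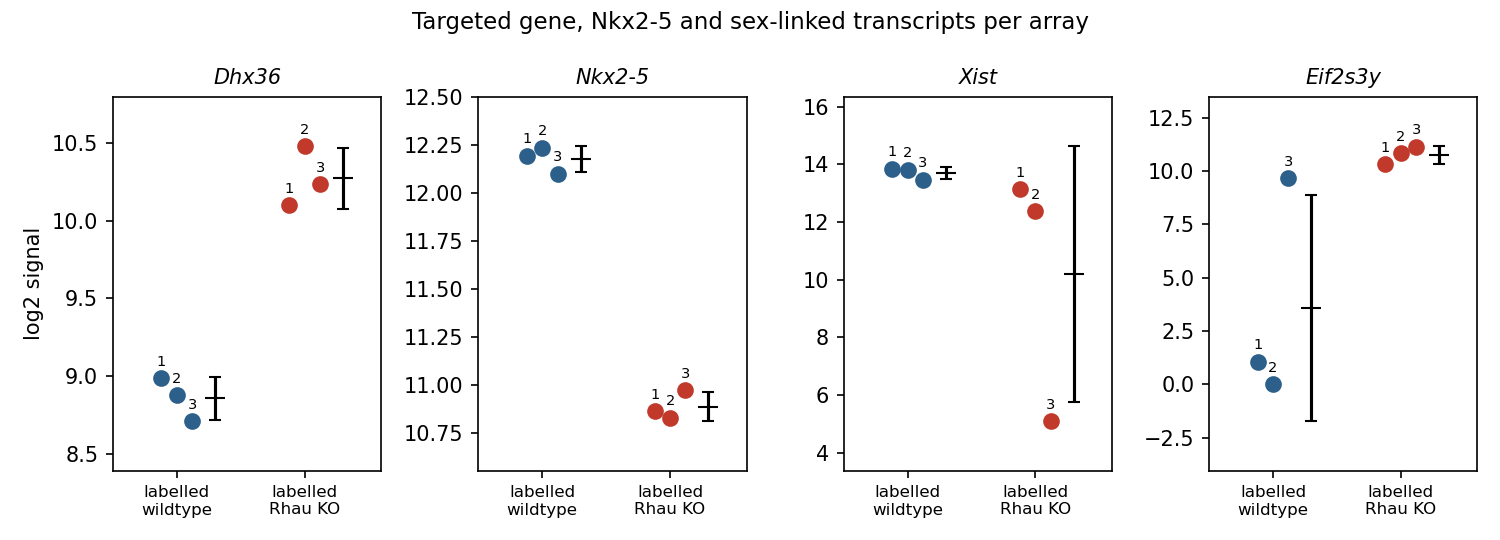
Log2 signal of Dhx36, Nkx2-5, Xist and Eif2s3y (vertical axes, each with its own range) in the 3 arrays labelled wildtype (blue) and the 3 labelled Rhau KO (red). Points are arrays with their replicate numbers, and bars give mean ± SD; Dhx36 averaged 8.86 against 10.27 and Nkx2-5 averaged 12.18 against 10.89, without overlap between the labels.

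Sex-linked transcripts differed between the arrays. Xist, the RNA made from the inactive X chromosome of female cells, was at 13.85, 13.82 and 13.47 in replicates 1 to 3 labelled wildtype and at 13.14, 12.37 and 5.10 in replicates 1 to 3 labelled Rhau KO. Eif2s3y, a Y-linked gene, was at 1.06, 0 and 9.66 in the arrays labelled wildtype and at 10.30, 10.83 and 11.12 in those labelled Rhau KO. The linear signal of Eif2s3y, Kdm5d and Uty, averaged as a percentage of the highest array, was 1.23, 2.04 and 39.3 under the wildtype label and 59.6, 82.8 and 100 under the Rhau KO label. Xist signal as a percentage of the highest array was 100, 98.0 and 77.2 under the wildtype label and 61.1, 35.8 and 0.232 under the Rhau KO label. Replicate 3 labelled wildtype and replicates 1 and 2 labelled Rhau KO thus carried both Xist and Y-linked signal, whereas cells of 1 embryo normally carry one or the other. The series text reads as 1 heart per array. Whether these arrays nevertheless hold RNA of more than 1 embryo is not given in the sources used here, and the p-values measure the spread between arrays. Ddx3y, the remaining member of the sex-linked list, was not among the tested genes.

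Arrays of one label resembled each other more than arrays of the other label. Pearson correlations across the 12416 tested genes ran from 0.987 to 0.990 within a label and from 0.977 to 0.979 between labels. These are correlations across genes, which are not independent replicates. The first principal component held 48.3% of the variance and separated the labels, and the second held 14.6%.

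Among the largest increases in the arrays labelled Rhau KO were the lysozyme genes Lyz1 and Lyz2, which encode bacteria-degrading enzymes, at 12.7-fold and 7.90-fold. The Lyz1 value comes from a probe set marked as shared with other transcripts, and the only Lyz1 probe set not so marked, at 4.45 and 5.52, lay below the filter. The proprotein convertase Pcsk6 was 4.19-fold higher and Col2a1, a cartilage collagen, 4.18-fold higher. Igfbpl1, the potassium channel gene Kcnd2, Slitrk5, Lin7a, the transcription factor gene Sox3 and Gm13889 were between 3.70-fold and 3.19-fold higher. The Y-linked genes Eif2s3y, Kdm5d and Uty had differences of 7.18, 4.89 and 3.36 on the log2 scale, with SDs of 5.30, 3.69 and 2.30 in the arrays labelled wildtype. Tnnt3, the fast skeletal troponin T, showed the largest decrease at 14.8-fold, from 10.98 ± 0.11 to 7.09 ± 0.49. Myom2, a protein of the sarcomere M-band, was 4.76-fold lower, and the claudin gene Cldn13 was 3.99-fold lower. Pde10a, Rfx2, 3110040M04Rik, the estrogen receptor gene Esr1, Kcnn4, Insyn2b, Hjv, Trim54, Cck and the acetyltransferase gene Kat5 were between 3.78-fold and 3.01-fold lower. Other probe sets above the filter differed by 0.10 for Rfx2, -0.50 for Pde10a, -1.15 for Esr1 and -0.99 for Kcnn4 without a call. Those of Hjv and Kat5 differed by -1.67 and -1.60 with a call. Adjusted p ranged from 1.94e-07 for Lyz2 to 0.0279 for Kdm5d over these 26 genes. Calls for Eif2s3y, Kdm5d, Uty, Kcnn4 and Cck were lost when 1 or another array was left out. In other such fits the call was kept at a smaller difference. Kdm5d stood at 2.99 without replicate 1 labelled wildtype and Kcnn4 at -1.07 without replicate 3 labelled Rhau KO. The mean signal of Lin7a, Eif2s3y, Kdm5d and Uty under the wildtype label and of Kcnn4, Insyn2b and Cck under the Rhau KO label lay below the filter level of 5.90, and Gm13889 under the wildtype label lay on it at 5.91, so these differences depend on signals near the lower end of the scale. With the Y-linked signal as a covariate Lin7a stood at 1.06, Gm13889 at 2.54, Pde10a at -0.83, 3110040M04Rik at -2.73, Kcnn4 at -0.82 and Hjv at -1.10, against 1.68, 1.67, -1.92, -1.79, -1.69 and -1.67 without it, and Eif2s3y, Kdm5d and Uty at -2.07, -0.93 and -0.83.

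In all, 1018 genes were higher and 1336 lower in the arrays labelled Rhau KO, 19.0% of the 12416 tested. At least 2-fold differences were found for 43 higher and 94 lower genes, for 19 and 51 with a pseudocount of 64 and for 13 and 62 with the lowest 60% of probe sets left out; testing every probe set gave 69 higher, and the Y-linked signal as a covariate 17 higher. The median fold was 1.28 among the higher and 1.31 among the lower genes. Groups did not overlap for 4609 genes, 37.1% of those tested, where chance gives 10%. Of 2400 other probe sets of the called genes, 1932 pointed the same way by sign alone. The test was passed by 658 in the same direction and by 23 in the opposite direction. The higher count was 590, 610 or 646 without replicate 1, 2 or 3 labelled wildtype and 664 without replicate 1 labelled Rhau KO, and averaging all probe sets of a gene gave 608 higher and 824 lower genes, eBayes without trend 614 and 878. With the Y-linked signal as a covariate the counts were 46 and 132, and in the 3 arrays with both Xist and Y-linked signal, where the wildtype label keeps 1 array, which is assumed to vary like the other label's, they were 298 and 448. Both of these alternatives were chosen after seeing the data.

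**Figure D2:**
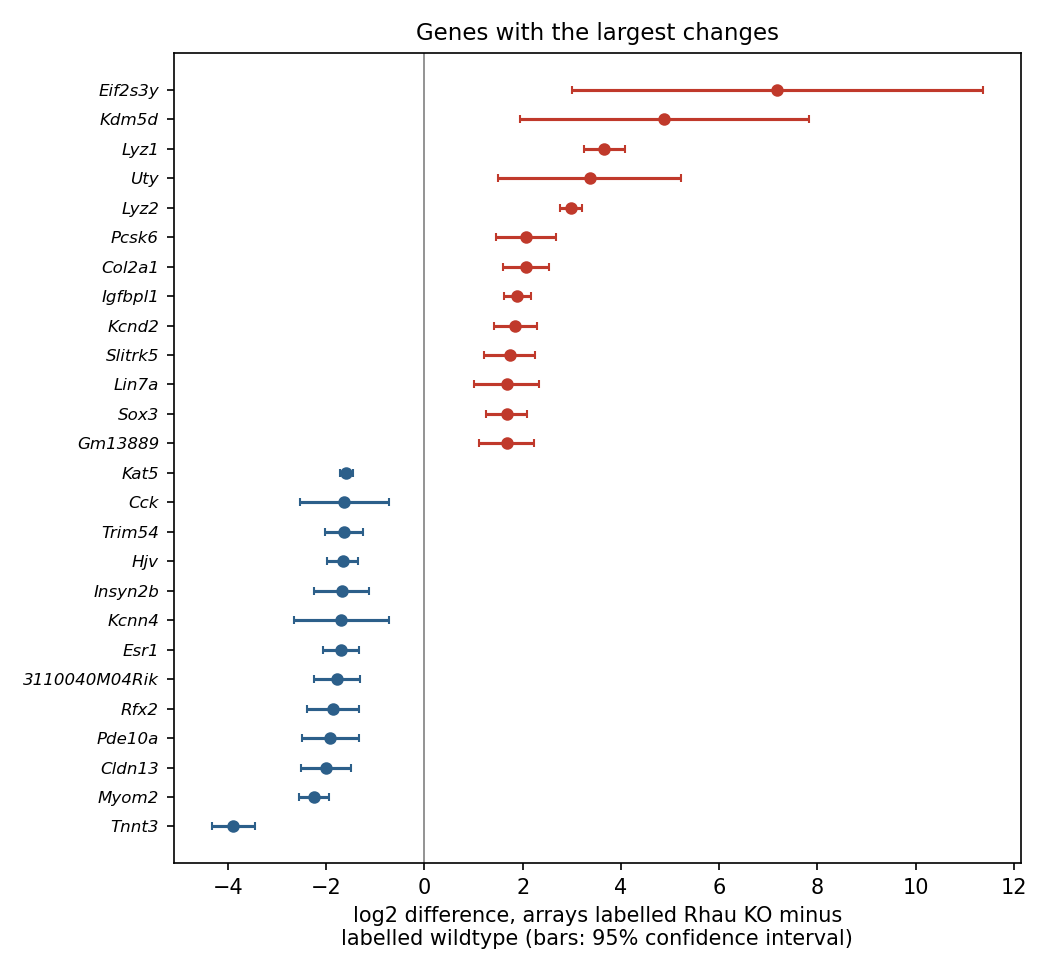
Log2 difference between the arrays labelled Rhau KO and labelled wildtype (horizontal axis) for the 13 largest increases (red) and 13 largest decreases (blue) among called genes with non-overlapping groups. Bars are 95% confidence intervals from limma; the Y-linked genes Eif2s3y, Kdm5d and Uty have the widest bars, and Tnnt3 lies lowest at -3.89.

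Cardiac transcription factors changed in both directions. Hey2, a Notch-responsive repressor of the compact ventricular wall, was 2.49-fold lower, close to Nkx2-5 itself, while Myocd, a coactivator of muscle genes, and Irx3 were 1.69-fold and 1.59-fold higher. Of 27 measured factors, 5 rose and 9 fell (5 and 10 adjusted over the list alone), and the list did not pass (median -0.05, adjusted p = 0.358). Among 14 measured genes reported to depend on NKX2-5, Kcne1 (0.84), Myocd and Hopx (0.19) rose and Ankrd1 (-0.31) fell, and 10 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.387). The atrial list had 1 member that rose and 5 that fell of 12 (1 and 6 adjusted over the list alone): Stard10 (-1.24), the potassium channel gene Kcna5 (-0.84) and Sln, a regulator of the calcium pump (-0.78), fell, and Pam (0.43) rose (adjusted p = 0.0805). In the ventricular list 3 of 11 rose and 1 fell (4 and 2 adjusted over the list alone), with Prdm16 at 0.90, Kcne1 at 0.84, Mpped2 at 0.63 and Hey2 at -1.32. Its median was -0.03, while its mean of 0.06 and the test pointed up (adjusted p = 0.538). In the NKX2-5, atrial and ventricular lists, some members without a call lay near the top of the measured signals, where saturation was not tested. The other Myocd probe set differed by 0.20 without a call, and other Prdm16 probe sets above the filter by 0.61 and 0.35 without a call. The calls for Hopx and Ankrd1 were lost when 1 array was left out, and with the Y-linked signal as a covariate Ankrd1 stood at 0.0157, Hopx at 0.11 and Sln at -0.50.

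Signalling genes of the developing heart likewise moved apart. Trabeculation, Notch and neuregulin genes had 4 members higher and 1 lower of 16, also when adjusted over the list alone: the guidance cue gene Sema3a (0.66), Adamts1 (0.31) and the Notch ligand gene Jag1 (0.24) rose, and Hey2 fell (adjusted p = 0.313). Jag1 stood at -0.04 when all of its probe sets were averaged, and its call was lost when 1 array was left out. Second heart field and outflow genes had 2 higher and 4 lower of 12, the same adjusted over the list alone, with Sema3c at 0.77, Plxnd1 at 0.39, Bmp4 at -0.49 and Nkx2-5 at -1.29 (adjusted p = 0.440). Cushion and valve genes had 4 higher and 1 lower of 21, unaltered when adjusted over the list alone, with Tgfbr3 at 0.60, Bmp2 at 0.38, Tgfb2 at 0.26 and Bmp4 falling (adjusted p = 0.508). Calls for Bmp2 and Tgfb2 were lost when 1 array was left out, and Bmp2 stood at 0.67 with the Y-linked signal as a covariate. Ion channel and calcium handling genes had 3 higher and 8 lower of 24 (3 and 9 adjusted over the list alone). Here Kcne1 rose, while Sln, the junctional protein gene Jph2 (-0.74) and Kcnj5 (-0.71) fell (adjusted p = 0.276). The other Jph2 probe set differed by -0.32 without a call.

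Genes of the contractile apparatus changed in part, most of those that passed being lower in the arrays labelled Rhau KO. Of 26 measured sarcomere genes 8 fell and 2 rose (14 and 4 adjusted over the list alone), with a median of -0.13. Many members without a call lay near the top of the measured signals, where saturation was not tested. Their values do not show that these transcripts did not differ. Myom2 fell 4.76-fold, the skeletal actin gene Acta1 fell from 14.16 ± 0.03 to 13.03 ± 0.15 and the chaperone gene Cryab changed by -0.43, while the titin cap gene Tcap rose by 0.48. The sarcomere list passed (adjusted p = 0.00148) but not with an estimated correlation (adjusted p = 0.545 with an estimated correlation). The skeletal muscle list had 4 measured members, of which Tnnt3 and the fast troponin I gene Tnni2 (-0.89) fell, also adjusted over the list alone (adjusted p = 0.0257, and adjusted p = 0.402 with an estimated correlation). Without Tnnt3, the member that moved most, the list had adjusted p = 0.314, and with a pseudocount of 64 adjusted p = 0.0820, with no filter 0.367 and with averaged probe sets 0.100. Of 9 smooth muscle genes 1 fell, Cnn1 at -0.36 (0 higher and 2 lower adjusted over the list alone; adjusted p = 0.313). In the same arrays the erythroid list had a median of -0.99 and the endothelial list one of 0.22.

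Genes of mitochondrial energy metabolism that passed were mostly lower, in arrays where the erythroid list had a median of -0.99 and the endothelial list one of 0.22. Of 22 measured oxidative phosphorylation genes 15 fell, 1 rose and 6 did not pass (16 and 1 adjusted over the list alone), with a median of -0.20. Subunit genes of cytochrome c oxidase, Cox8b and Cox7a1, fell by 0.60 and 0.45, and Ndufa9, of the first respiratory complex, fell by 0.32. Ppargc1a, a coactivator that promotes mitochondrial gene expression, rose by 0.68. The list passed (adjusted p = 7.94e-06), though not with an estimated correlation (adjusted p = 0.402 with an estimated correlation). Of 14 fatty acid oxidation genes 8 fell, 1 rose and 5 did not pass, the same adjusted over the list alone, with a median of -0.19. The fatty acid transporter gene Cd36 was at -0.94, Cpt2 at -0.38 and Acadl at -0.38, and the lipase gene Lpl at 0.37. That list passed (adjusted p = 8.97e-04, and adjusted p = 0.402 with an estimated correlation), and averaged probe sets gave adjusted p = 0.0668. Hypoxia and glycolysis genes had 2 lower of 21, also adjusted over the list alone: Ndrg1 (-0.64) and Aldoa (-0.19; adjusted p = 0.231). Calls for Cpt2 and Aldoa were lost when 1 array was left out. With the Y-linked signal as a covariate Cpt2 stood at -0.0124, Acadl at -0.20, Ndrg1 at -0.10, Cox8b at -0.23 and Cox7a1 at -0.19. With the Y-linked signal as a covariate, adjusted p was 0.0715 each for the sarcomere, oxidative phosphorylation and fatty acid oxidation lists. Y-linked signal averaged 66.6 percentage points higher in the arrays labelled Rhau KO.

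Markers of red blood cells were lower in the arrays labelled Rhau KO, with a median of -0.99. Of 13 measured erythroid genes 10 fell and 0 rose (11 and 0 adjusted over the list alone). Epb42 was 2.97-fold lower, Alas2, the erythroid enzyme that starts heme synthesis, 2.61-fold, the anion exchanger gene Slc4a1 2.42-fold and Ermap 2.19-fold. The embryonic globin gene Hbb-bh1 fell by 0.59, while Hbb-y and Hba-x, at 15.15 and 14.54 in the arrays labelled wildtype, differed by -0.10 and -0.10 without a call. Both lie near the top of the measured signals, where saturation was not tested, so these values do not show that the transcripts did not differ. These 3 globin genes are named outside the rule, after their values were seen. Alas2 was at 9.02, 9.62 and 10.16 in replicates 1 to 3 labelled Rhau KO and between 10.82 and 11.25 in the arrays labelled wildtype. With the Y-linked signal as a covariate Epb42, Alas2, Slc4a1 and Ermap stood at -2.77, -2.63, -2.41 and -2.11, against -1.57, -1.39, -1.27 and -1.13 without it. The erythroid list passed (adjusted p = 1.65e-07, and adjusted p = 0.402 with an estimated correlation).

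Of 19 measured endothelial markers 8 rose, 0 fell and 11 did not pass (9 higher and 0 lower adjusted over the list alone), with a median of 0.22: the receptor gene Kdr rose 1.54-fold, Cdh5, the cadherin of endothelial junctions, 1.42-fold, Npr3 1.33-fold and Sox18 1.28-fold. The other Cdh5 probe set differed by -0.07 without a call. The list passed (adjusted p = 3.26e-04, and adjusted p = 0.402 with an estimated correlation). Of 14 macrophage and leukocyte genes, Lyz2 (2.98) and Mrc1 (0.43) rose and 12 did not pass, also when adjusted over the list alone. The macrophage list had adjusted p = 0.00723, adjusted p = 0.545 with an estimated correlation and, without Lyz2, adjusted p = 0.0784; its median of 0.26 turned to -0.01 with the Y-linked signal as a covariate. Neural crest and neuronal genes had 3 higher and 0 lower of 7, the same adjusted over the list alone: the endothelin receptor gene Ednrb (0.78), Elavl4 (0.63) and Gap43 (0.32; adjusted p = 0.0805). Fibroblast and matrix genes had 1 higher and 3 lower of 19 (2 and 4 adjusted over the list alone), with Col6a1 at -0.37, Col6a2 at -0.31, Pdgfrb at -0.25 and Dcn at 0.23. The median of that list was 0.01, while its mean of -0.03 and the test pointed down (adjusted p = 0.567). No member of the epicardium list (12 measured, Aldh1a2 at -0.31 and Upk1b at -0.20; adjusted p = 0.440) or of the liver, lung and gut epithelium list (6 measured, Epcam at -0.74 and Ttr at -0.41; adjusted p = 0.508) passed, with 0 and 0 adjusted over the list alone. Upk1b stood at 0.01 when its probe sets were averaged. Calls for Sox18, Mrc1, Elavl4, Gap43, Col6a2, Pdgfrb and Dcn were lost when 1 array was left out. The covariate put Kdr at 0.29 (from 0.63), Sox18 at 0.16 (from 0.36), Mrc1 at 0.25, Elavl4 at 0.15, Gap43 at 0.59, Col6a1 at -0.23, Col6a2 at -0.61, Pdgfrb at -0.42 and Dcn at 0.12.

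**Figure D3:**
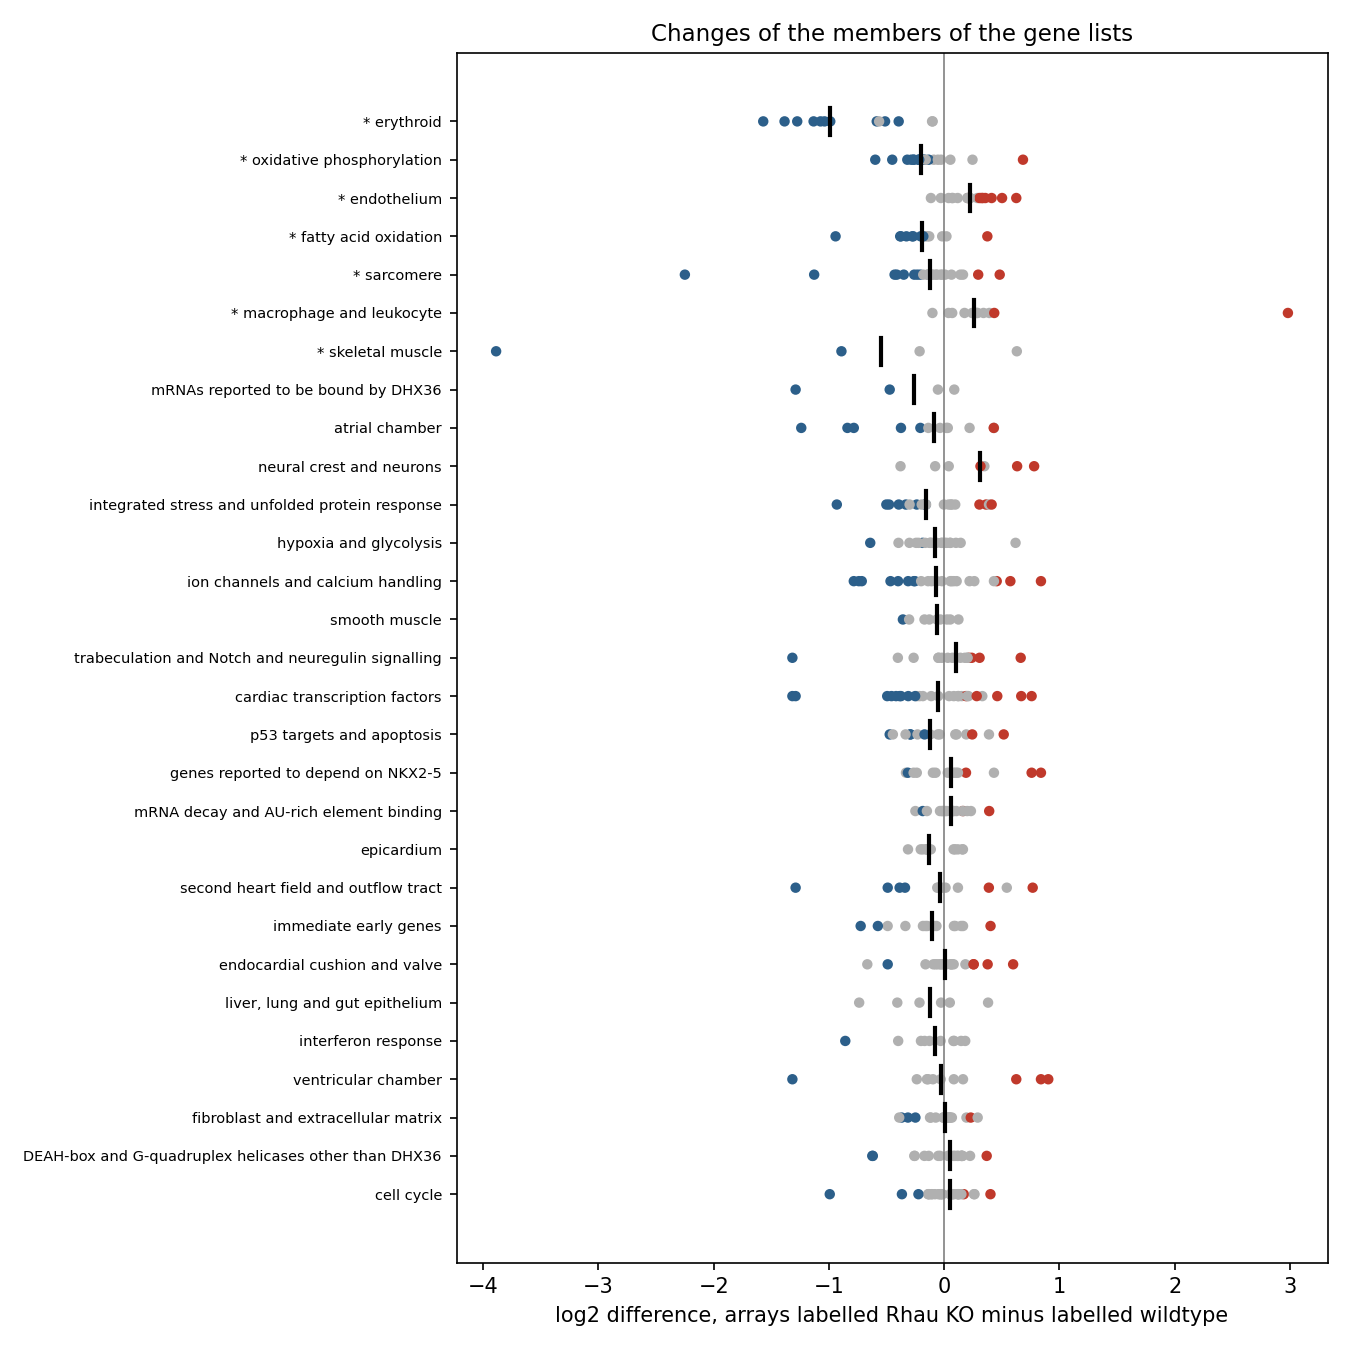
Log2 difference, arrays labelled Rhau KO minus labelled wildtype (horizontal axis), of each measured member (points) of the 29 tested lists (rows, ordered by p). Red points rose, blue points fell, grey points did not pass, black bars are medians and asterisks mark the 7 lists past the test with the preset correlation; the erythroid median lies at -0.99 and the endothelial one at 0.22.

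Other DEAH-box and G-quadruplex helicases had 2 members lower and 1 higher of 23, also adjusted over the list alone. Dhx9 and Dhx15 fell by 0.62 each and Dhx33 rose by 0.37. The median was 0.05, while the mean of -0.01 and the test pointed down (adjusted p = 0.902). Of 4 measured mRNAs reported to be bound by DHX36, Nkx2-5 and the cell cycle inhibitor gene Cdkn1a (-0.47) fell, the same adjusted over the list alone (adjusted p = 0.0805). The other Cdkn1a probe set differed by 0.03 without a call. Genes of mRNA decay and AU-rich element binding had 2 higher and 1 lower of 19, also adjusted over the list alone. Parn (0.39) and Elavl1 (0.16) rose and Hnrnpd (-0.19) fell (adjusted p = 0.389). Hnrnpd stood at 0.25 when all of its probe sets were averaged. Its other probe sets pointed up, by 0.12 without a call and by 0.80 with a call. Cell cycle genes had 2 higher and 3 lower of 29 (2 and 2 adjusted over the list alone), with the proliferation marker Mki67 at -0.99, Mcm2 at 0.40, Ccnd3 at -0.37 and Bub1 at -0.22. Their median of 0.05 and the test pointed up and their mean of -0.01 down (adjusted p = 0.971). The Y-linked covariate put Dhx33 at 0.24, Parn at 0.24, Mcm2 at 0.19 and Bub1 at -0.43.

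None of the stress pathway lists passed the test, which looks for a shift of a list in a shared direction. Integrated stress and unfolded protein response genes had 3 higher and 8 lower of 21 (3 and 9 adjusted over the list alone), with Trib3 at -0.93, Herpud1 at -0.50, Ddit4 at -0.48 and Vldlr at 0.41 (adjusted p = 0.162). The p53 list had 2 higher and 4 lower of 17 (2 and 5 adjusted over the list alone): Trp53inp1 (0.52) rose, and Cdkn1a, Perp (-0.29) and Phlda3 (-0.29) fell (adjusted p = 0.358). Among 15 immediate early genes Egr1 (-0.72) and Ier3 (-0.58) fell and Nr4a1 (0.40) rose, also adjusted over the list alone (adjusted p = 0.440). Perp and Ier3 stood at 0.0401 and 0.13 with the Y-linked signal as a covariate, Trp53inp1 at 0.80, Trib3 at -1.60, Egr1 at -0.32 and Rsad2 at -1.34. Of 10 interferon response genes Rsad2 (-0.86) fell, the same adjusted over the list alone (adjusted p = 0.534). Calls for Cdkn1a, Elavl1, Hnrnpd, Parn, Bub1, Perp, Phlda3 and Ier3 were lost when 1 array was left out, that for Elavl1 whichever array it was.

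In all, 7 of 29 lists passed the test with the preset correlation, 5 lower and 2 higher in the arrays labelled Rhau KO, and 0 passed with an estimated correlation, while 13 did by fry, which does not compare a list with other genes. At an unadjusted p under 0.05, the estimated correlation left 2 lists, endothelium and fatty acid oxidation. Dhx36 ran against the label from which these directions are drawn.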

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

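Among 4226 probe sets above the filter that name no gene or several, which no comparison above uses, 327 were higher and 112 lower in the arrays labelled Rhau KO than in the control arrays labelled wildtype (limma over 27020 probe sets above the filter). They are listed here because they lie outside the measured genes. The share past the test was 10.4%, against 13.6% of all probe sets above the filter. The largest rise was 6.79 and the largest fall -3.13 on the log2 scale. Groups of 3 arrays are too small to flag a single outlying array by the spread of its group.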

How the results depend on the processing

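Dhx36 and Nkx2-5 kept direction and call under every alternative run, at 1.14 to 1.58 and -1.33 to -1.26. Counts moved by over 1.5 times under these settings, and the cause was not tested unless the construction shows it. A pseudocount of 64, which shrinks low signals, left 19 higher and 51 lower genes at 2-fold or more. Filtering the lowest 60%, which tests fewer genes, left 13 and 62. Averaging probe sets gave 608 higher and 824 lower genes, testing every probe set 1550 higher (69 at 2-fold or more), and eBayes without trend 614 and 878. Leaving out each array gave 590 to 802 higher genes, of which the 745 and 802 without replicates 2 and 3 labelled Rhau KO stayed within 1.5 times. Lists past the test numbered 0 with an estimated correlation and 13 by fry, against 7. Chosen after seeing the data, the Y-linked covariate gave 46 higher and 132 lower genes (17 higher at 2-fold or more) and 2 lists, and the 3 arrays with both Xist and Y-linked signal gave 298 and 448 genes; both leave fewer degrees of freedom, and with a lone wildtype array assumed to vary like the others the latter says little about stability, for Dhx36 and Nkx2-5 too. Averaging probe sets turned Jag1 (-0.0368), Upk1b (0.0111) and Hnrnpd (0.25). The covariate turned Eif2s3y (-2.07), Kdm5d (-0.93), Uty (-0.83), Ankrd1 (0.0157), Upk1b (0.0247), Ttr (0.26), Perp (0.0401) and Ier3 (0.13). Of 102 other called genes named, the covariate made 14 changes larger and 21 smaller by over 1.5 times and turned 6. Whether these moves exceed the larger SE with the covariate was not tested. Over 106 other named genes, 1816 of 2088 values kept direction and side of the threshold, 258 lost the call and 3 gained one. Of 102 called genes 59 kept the call under every setting listed before the data were examined in which they were tested. Some of these, such as Kcnd2, were not tested in all of those settings. The replicate block gave 955 higher and 1300 lower genes and 6 lists, without skeletal muscle (camera, adjusted p = 0.0510). The labels state no pairing. Deviations of same-numbered arrays correlated at -0.01, 0.04 and 0.01, and 2 of 3 arrays labelled wildtype correlated best with their own number. Y-linked signal rose with the replicate number under both labels. With 3 arrays per label, these values do not exclude structure shared by same-numbered arrays. Signals near the lower end of the scale limit what can be called there.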

Other observations

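Tests of other splits and of the chromosome region were set down before their results were seen; those of the Dhx36 labels, of the male share on the linear scale, of macrophages and of shared lysozyme probes were chosen only after the result was seen. The gene families below were chosen after their values were seen. Troponin subunits, which make the thin filament respond to calcium, did not change together in the arrays labelled Rhau KO. Of 7 measured subunit genes 4 fell and 1 rose. Tnnt3 and Tnni2, the fast skeletal forms, fell by 3.89 and 0.89, and the cardiac forms Tnni3 and Tnnc1 fell by 0.26 and 0.23. Tnnt1, the slow skeletal form, rose 2.83-fold, from 11.29 ± 0.14 to 12.79 ± 0.21 (n = 3 each, adjusted p = 7.06e-06). Tnnt2, near the top of the measured signals where saturation was not tested, and Tnni1 differed by -0.13 and -0.15 without a call.

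Of 8 measured enzymes of heme synthesis 7 fell, Alas2, itself in the erythroid list, by 1.39, Fech by 0.79, Ppox by 0.56, Uros by 0.51, Cpox by 0.48, Alad by 0.34 and Urod by 0.34, and Alas1, the form of other tissues, stood at -0.16 without a call. Of 5 measured Slit and Robo genes 2 rose, Slit2 1.81-fold and its receptor gene Robo1 1.71-fold, and of 2 netrin genes Ntn1 rose 1.83-fold, while Robo2, Robo4, Slit3 and Ntn4 did not pass. Of 7 class 3 semaphorins 3 rose, Sema3c (0.77), Sema3a (0.66) and Sema3b (0.53). Dhx36 ran against the label from which these directions are drawn.

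Dhx36 signal was higher where the label says the gene was deleted. A single wrong label is argued against by the arrays themselves, since the lowest correlation within a label (0.987) exceeded the highest between labels (0.979). An exchange of both groups' labels may account for it and cannot be told apart from the labels as given, because the smallest difference among the Dhx36 probe sets was 0.90 and an exchange only turns every sign. Probe sets outside the deleted part would leave the signal unaltered and are argued against as the whole cause of the rise, since the 95% intervals of the 3 probe sets ran from 0.70 to 1.65. A higher level of a shortened transcript that such probe sets read was not tested and stays open, since the deleted part is not given in the sources used here.

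The labels differ in sex-linked signal as well as in genotype, so the male share of the hearts is a candidate explanation for the 2354 called genes. Within a label, the linear signal of the 2268 called autosomal genes should then follow Y-linked signal by about the slope the label change needs. That is a ratio near 1. The ratio was -0.067 within the wildtype label and -0.042 within the Rhau KO label (0.074 and 0.055 for contrasts unrelated to that signal). Xist, which must follow the share, had 0.651 and 1.67. Genes are called where spread within a label is small, which draws this ratio toward 0, and Xist was not chosen so. The called genes as a set thus did not follow Y-linked signal within a label, which does not settle the share as their cause. With the covariate the median change of the autosomal genes on the log2 scale was 0.994 times that without it. Their median SE went from 0.075 to 0.163, and 170 of the 2354 calls were made again. Single genes such as Cpt2 (-0.0124) moved close to 0, but whether such moves exceed the larger SE was not tested. These covariate values rest on the same choice of genes. On the first principal component, arrays labelled wildtype lay at -20.96, -17.83 and -15.49. Their Y-linked signals were 1.23, 2.04 and 39.3% of the highest. Those labelled Rhau KO lay at 17.89, 18.41 and 17.98, at 59.6, 82.8 and 100%. The component thus jumped between the labels and moved little with that signal within them. This argues against the male share as the main source of the separation on that component. For single called genes the male share stays open, and genotype remains among the open explanations. Grouping the arrays in the 10 possible splits is too few for a share under 0.05. Of these splits 1, the real one, gave 2354 genes and the highest other 0. For lists 2 splits gave as many, the real one with 7 and the highest other also with 7. That other split joins replicate 1 labelled Rhau KO with replicates 1 and 2 labelled wildtype. The splits other than the real one put 2 to 7 lists past the test, each with 0 genes called. Lists thus pass with the preset correlation where no gene is called. These splits hold the labels in unequal numbers, so part of the label difference remains in them.

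Lyz2 and Lyz1 rose by 2.98 and 3.66 in the arrays labelled Rhau KO. More macrophages are argued against as the source, since the other 13 measured macrophage and leukocyte markers had a median change of 0.26 (SD 0.15) and a highest of 0.43. Of the 20 nearest tested genes on the chromosome 20% were called (4 genes), close to the 19.0% of all tested genes. That share gave no sign of an altered chromosome region around the genes, and so few genes do not exclude one. For Lyz1, probe sets that also read Lyz2 RNA may account for the rise, because 2 of its 3 probe sets are marked as shared and the remaining one averaged 4.99, below the filter, at 4.45 and 5.52. Genotype, as the labels give it, stays open for Lyz2.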
